A study of Homo sapiens with 6 samples.

How the data were processed

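Gene expression was measured in OCI-LY10, a human cell line derived from a diffuse large B-cell lymphoma of the activated B cell-like type. Cells were cultured with pimasertib, an inhibitor of the kinases MEK1 and MEK2, or with the solvent DMSO. RNA was hybridised to Illumina HT-12 bead arrays, with 1 array per treatment at 4, 8 and 12 h, or 6 arrays in all. Groups and times were taken from the labels of each sample. Per the labels' protocols, total RNA was purified on columns, checked for integrity, and amplified to biotinylated cRNA. The labels do not say that the 3 times came from separate cultures, so p-values measure only the spread between these arrays, which may be partly technical.

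The deposited values of the authors are log2 intensities of 47231 probes, from 6.20 to 13.91. The sorted values of the 6 columns differ by at most 9e-04, so the authors' log2 values had been quantile-normalized between arrays. Base 2 was inferred from this range, since a natural log would put the brightest probe above the 65535 steps of a 16-bit scanner. The software, the background correction and the method of normalization are not given in the sources used here. A table of intensities before normalization was not used. Its 6 value columns carry names that match no label, and it was found to hold no detection p-values. The planned background correction with detection p-values was therefore replaced by the series' normalized values, as had been foreseen. For arrays, their number limits the precision.

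Because no detection p-values were at hand, dim probes were removed with a rule set after the values had been seen and before any treatment test. The most frequent log2 value was 6.49, and the values below it gave a background SD of 0.0703. A probe was kept if it exceeded 6.70, which is 3 SDs above that mode, in at least 3 of the 6 arrays. This left 19814 probes. The platform annotation gave 1 gene for 30113 probes, several for 8 and none for 17110. Of the named probes, 30074 were matched by gene identifier to current RefSeq names and 0 symbols changed. For each of 11069 genes the kept probe of the highest mean was used, and 2853 genes had several kept probes.

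The treatment effect was the coefficient for pimasertib minus DMSO in limma 3.58.1 (R 4.3.3, statmod 1.5.0), fitted to all 6 arrays with the time point as a 3-level factor. This leaves 2 residual degrees of freedom, and the empirical Bayes step pools variances over genes. The residual measures how far the treatment difference varies between the 3 times. A real change of the effect with time therefore counts as error in each SE and p-value, which do not measure replicate noise alone. P-values are two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For genes of a list, adjustment was also made over the list alone. No adjustment was made across the 26 lists tested, so some calls over a list alone could arise by chance. Both time slopes, of the treatment difference and of DMSO alone, were tested in a model of treatment, hours and their product. At single times there is 1 array per treatment, so differences there are values without a test. In this design the time point is the block that pairs each pimasertib array with a DMSO array, and a fit without it was run as an alternative.

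Before the data were examined, 29 gene lists were fixed, and 26 of them had at least 5 measured members. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera refers its statistic to the residual degrees of freedom, 2 here, so a list could hardly pass. The rule for naming genes was also fixed then. It takes up to 10 genes per direction of the largest difference past the threshold with the same sign at all 3 times, filled by the smallest p where fewer pass. It adds up to 4 members per list of the smallest p, 13 genes named whatever their values, and for each slope the 3 genes of smallest p per direction where fewer than 5 pass. Not every gene that the rule takes is printed below. Genes named outside the rule are marked as chosen after their values were seen.

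The alternatives tried were no filter on dim probes, a filter on all 6 arrays, the mean over kept probes, a trended and robust variance prior, other thresholds, hours as a linear covariate, no time block, and each time pair left out. Added after seeing the data were array weights, a fit with both the DMSO array of 8 h and the time point left out, an estimated correlation for the lists in each alternative, cyclic loess, normexp with an offset of 50 on the unlogged values, and a stricter background threshold of 6.91. In 1 of the fits with array weights, the estimate of the weights stopped before it converged. A value of a gene or list that changed sign without passing the threshold in either fit was not counted as reversed.

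The tests were tried on simulated data for 11069 genes with the real means. Noise was drawn from a normal distribution, with variances already pooled over genes by the empirical Bayes step. With the noise of each array as estimated from the data, the treatment test recovered 63 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 2 false calls. In the real data EGR1 and PTPN6, 3.74- and 3.85-fold lower, did not pass (adjusted p = 0.265, limma). A count of 0 calls there does not exclude changes of about 4-fold. The test of the slope difference recovered 0 of 100 genes whose treatment difference grew 2-fold over 8 h and 0 of 100 for 4-fold. With equal noise it recovered 6 of 100 and 87 of 100. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.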

Results

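The series profiled 1 lymphoma cell line, OCI-LY10, treated in culture with the MEK inhibitor pimasertib or with DMSO. MEK is the kinase that activates ERK, the last kinase of the RAS-MAPK cascade. The series title places the arrays within a study of pimasertib combined with inhibitors of BTK or PI3K-delta, kinases of B cell receptor signalling. Each treatment had 3 arrays, 1 each at 4, 8 and 12 h, and no treatment and time was repeated. Values are log2 intensities that the authors had quantile-normalized, and 11069 genes exceeded the background threshold of 6.70. Quantile normalization gives every array the same median of 6.63 over all probes.

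The first question was which genes differed between pimasertib and DMSO over the 3 times. The lower genes of smallest p were led by EGR1, an immediate early transcription factor induced by ERK, and PTPN6, which encodes the phosphatase SHP-1 that restrains B cell receptor signalling. EGR1 averaged 8.65 in DMSO and 6.74 with pimasertib, a log2 difference of -1.90 ± 0.20 (SE, 3 arrays per group), or 3.74-fold lower. With pimasertib, EGR1 was above the background threshold in 2 of 3 arrays, and its 12 h array lay below it. PTPN6 averaged 10.64 and 8.70, a difference of -1.94 ± 0.22 (SE), or 3.85-fold lower. Both were lower at 4, 8 and 12 h, with EGR1 at -1.45, -2.03 and -2.23 and PTPN6 at -1.40, -2.13 and -2.30. In limma over all 11069 genes the adjusted p was 0.265 for each, so neither passed. The 2 other PTPN6 probes did not pass the filter on dim probes, exceeding background in 0 and 1 arrays, and give no check of this value.

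The rest of the 10 lower genes did not pass either, each with an adjusted p of 0.645 in limma. NFATC1, a transcription factor activated through calcium and calcineurin, was at -1.02 ± 0.17 (SE), and its 2 other kept probes were at -0.46 and -1.11. DUSP2, a nuclear phosphatase that acts on ERK, was at -0.92 ± 0.17. BIK, a pro-apoptotic BH3-only gene, was at -1.03 ± 0.22 and SGK1, a serum-inducible kinase, at -0.94 ± 0.20. The 2 other kept probes of SGK1 were at -1.06 and -0.96. LTA, which encodes lymphotoxin alpha, was at -0.78, LRRFIP1 at -1.05, and the matrix metalloproteinase MMP7 at -0.90 with its other probe at -0.50. TDP1, a DNA repair enzyme, was at -0.85, and its 2 other kept probes were at 0.03 and -0.09. Their mean levels of 7.01 and 6.76 lie near background, as does that of the NFATC1 probe at -0.46, with 6.99.

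The 10 higher genes of smallest p likewise did not pass, each at an adjusted p of 0.645 in limma. DOCK10 was 2.52-fold higher at 1.34 ± 0.30 (SE). The ubiquitin ligase MARCHF7 was at 1.04, SEPHS1 at 0.86, POLR2B, a subunit of RNA polymerase II, at 0.86, and BTF3L4 at 0.84. WDR36, a ribosome biogenesis factor, was at 0.80, and CLINT1, POT1, RHOT1 and COBLL1 lay between 0.74 and 0.77. For SEPHS1, POT1 and BTF3L4 the other kept probe gave 0.11, -0.02 and 0.25, and the 3 others of RHOT1 gave 0.09, -0.19 and 0.67. The other POT1 probe and the RHOT1 probe at -0.19 have mean levels of 6.67 and 6.70, below and barely below the background threshold, and give no check.

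**Figure D1:**
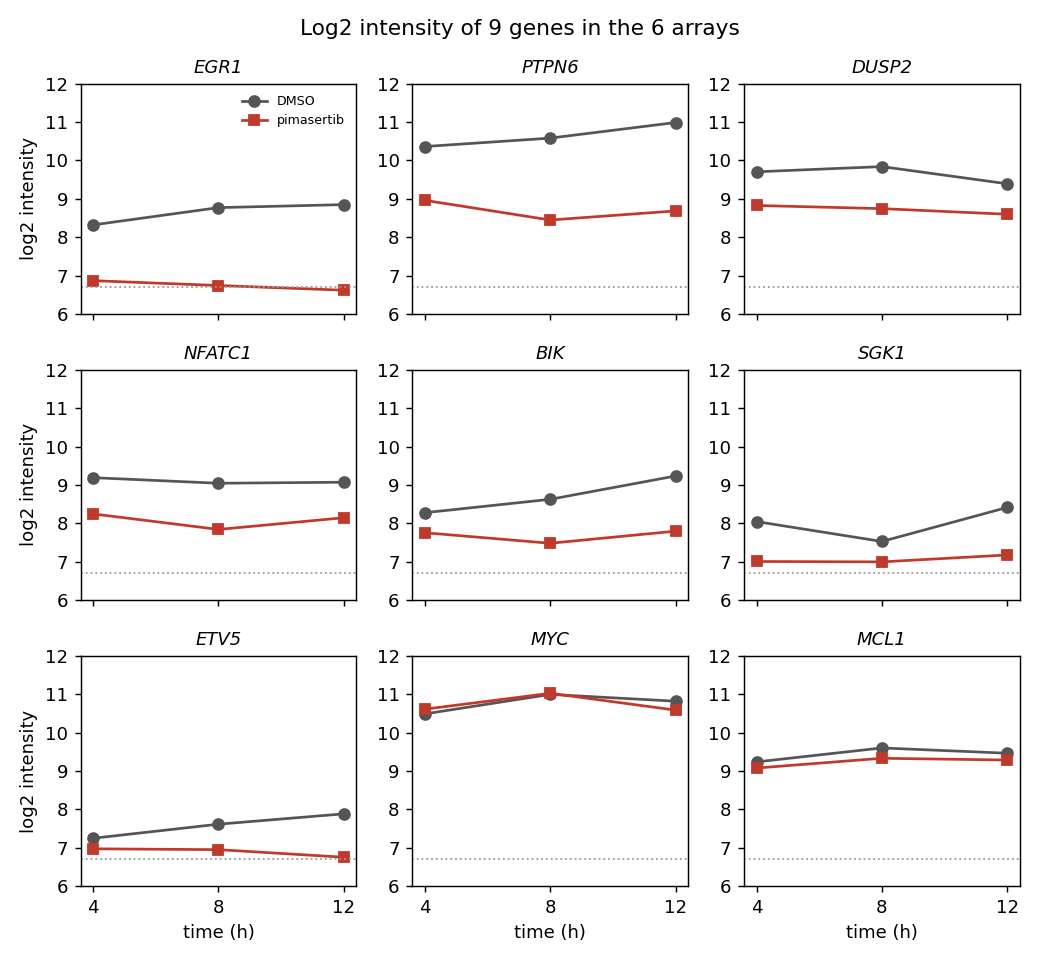
Log2 intensity (vertical axis) against time in hours for 9 genes, with 1 array per point, DMSO in grey circles and pimasertib in red squares; the dotted line is the background threshold of 6.70. EGR1 and PTPN6 were lower with pimasertib at all 3 times, while MYC differed by 0.12, 0.03 and -0.23 at 4, 8 and 12 h.

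Over all genes, 0 passed an adjusted p of 0.05 in limma, and 831 had an unadjusted p under 0.05 (438 higher and 393 lower), against a 5% share of 553.4. With the noise of each array as estimated, 402 of 10851 unchanged simulated genes had such a p, so 553.4 is not a firm chance count. In 1836 genes, or 16.59%, the 3 pimasertib arrays lay all below (908) or all above (928) the 3 DMSO arrays, where chance gives 10%. An exact test of 3 against 3 cannot give a p below 0.1. At least 1.5-fold apart in the same direction at all 3 times were 12 genes, 9 lower and 3 higher. The 3 higher ones, chosen after their values were seen, were CLINT1, POT1 and the cell cycle repressor RB1. The count of calls was 101 without the 12 h pair, in a fit with 1 residual degree of freedom where the variances were pooled over all genes (median total degrees of freedom 11069, against 6.97 with all pairs). It was 2 with a trended and robust variance prior, those 2 being EGR1 and PTPN6. The DMSO array of 8 h stood apart, with a mean correlation over genes of 0.914 with the other arrays against 0.944 to 0.969 for the rest. Of 142 named genes, the mean difference changed sign or by more than 1.5 times in 26, 43 and 46 when the 4, 8 or 12 h pair was left out, so many values below rest on 1 pair.

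Genes known to follow ERK activity were the next question. Among 18 measured members of the list of ERK feedback and output genes, 9 were lower and 3 higher at all 3 times. Here and below, such counts were not set against the share over all genes, so alone they show no shift of a list. KCNN4, a calcium-activated potassium channel, was at -0.75, MAFF at -0.62, ETV5 at -0.69 and DUSP5 at -0.41, and none passed over all genes or adjusted over the list alone. Second probes near background were at 0.23 for ETV5 and -0.13 for MAFF. The list's mean difference was -0.18, with medians of -0.07, -0.19 and -0.13 at 4, 8 and 12 h. It did not pass camera in limma at an adjusted p of 0.0822, and the adjusted p was 0.705 with an estimated correlation. That correlation, -0.0366, was below the preset 0.01, so the rise reflects the 2 residual degrees of freedom used there. DUSP6, a phosphatase of the same feedback loop, was measured close to background, at 6.84 in DMSO and 6.96 with pimasertib (0.12 ± 0.16, SE). DUSP4, SPRY2, SPRY4 and FOS did not exceed background in 3 arrays and have no value here.

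Of 22 immediate early genes, 5 were lower and 0 higher at all 3 times. EGR1 and DUSP2 fell when adjusted over the list alone (adjusted p = 0.000763 and 0.0104, limma), against 0.265 and 0.645 over all genes. IER5 was at -0.44 and the stress-induced ATF3 at 0.48, and neither passed. The list did not pass camera (adjusted p = 0.165, limma). Without the 4 h pair the DUSP2 call was lost (adjusted p over the list alone = 0.111, limma). EGR1 was not measurable where all 6 arrays had to exceed background.

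B cell receptor and PI3K genes form the next group. Of 26 measured receptor components, 8 were lower and 1 higher at all 3 times. PTPN6 fell when adjusted over the list alone (adjusted p = 0.00125, limma). The guanine exchange factor VAV1 was at -0.46, CD72 at -0.49 and PIK3CD, which encodes the p110-delta subunit of PI3K, at -0.37. Among 22 PI3K-AKT-mTOR genes, SGK1 passed as lower only when adjusted over the list alone (adjusted p = 0.0461, limma), against 0.645 over all genes. This was not adjusted across lists. TSC2 was at -0.35 and PIK3CB at 0.37. Among 24 RAS-MAPK components 9 were higher and 3 lower at all 3 times, with HRAS at -0.74, PTPN11 at 0.48 and ETS1 at 0.47. The other kept ETS1 probe was at 0.002. None of these 3 lists passed camera (adjusted p = 0.315, 0.511 and 0.407, limma). The SGK1 call was lost in 6 of 15 alternatives, with an adjusted p over the list alone of 0.426 without the 4 h pair, 0.133 without the 12 h pair and 0.0809 without the time block (limma).

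In the BCL2 family, 17 members were measured. BIK passed as lower only when adjusted over the list alone (adjusted p = 0.0348, limma, not adjusted across lists), against 0.645 over all genes. BCL2L13 was at 0.72, PMAIP1, which encodes the BH3-only protein NOXA, at 0.60 with its other probe at -0.03, and BAX at -0.43 with its other probe at -0.48. BCL2L11, which encodes BIM, was at 0.06 ± 0.22 (SE) and the anti-apoptotic MCL1 at -0.20 ± 0.16. Other kept probes differed from these, at -0.31 and -0.41 for BCL2L11 and at 1.002 for MCL1. The list did not pass (adjusted p = 0.861, limma), and its median of 0.03 and mean of -0.01 differ in sign. The BIK call was lost in 6 of 15 alternatives, with an adjusted p over the list alone of 0.0966 without the 8 h pair, 0.0508 without the 12 h pair and 0.0572 without the time block (limma).

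Lymphoma identity and NF-kB genes went both ways. Of 27 NF-kB targets, 4 were higher and 4 lower at all 3 times, with LTA at -0.78, BCL3 at -0.61, NFKB1 at 0.74 (0.40, 1.47 and 0.34 at 4, 8 and 12 h) and NFKBIZ at 0.49, whose other probe was at 0.11. Of 21 genes typical of the activated B cell-like subtype, 5 were lower and 1 higher at all 3 times, with IL16 at -0.52 and its other probe at -0.27, SPIB at -0.47 and PTPN1 at 0.58. IRF4, a transcription factor on which this subtype depends, was at -0.13 ± 0.17 (SE). Of 11 germinal centre genes 2 were higher and 2 lower at all 3 times, with BCL6 at 0.48 and RGS13 at -0.39. STAP1, below background in all pimasertib arrays, was at -0.35 and SSBP2 at -0.29. Among plasma cell genes ELL2 was at 0.61, TNFRSF17, above background in 2 of 3 DMSO arrays, at 0.57 and POU2AF1 at -0.61. In the list of B cell migration and adhesion genes the activation marker CD69, above background in 2 of 3 pimasertib arrays, was at -0.98. The integrin chain ITGB1 was at 1.09 and ITGB2 at -0.60, with their other probes at 0.55 and -0.29. No member passed over all genes or adjusted over the list alone. Camera gave adjusted p of 0.511 for NF-kB targets, 0.204 for subtype genes, 0.861 for germinal centre genes, 0.511 for plasma cell genes and 0.939 for migration genes (limma).

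MYC and cell cycle genes showed no call. MYC averaged 10.77 in DMSO and 10.74 with pimasertib (-0.03 ± 0.17, SE), and CCND2, which encodes cyclin D2, was at -0.15 ± 0.20. Their other kept probes were at 0.16 for MYC and -0.11 for CCND2. In the list of 30 ribosome biogenesis and MYC-linked growth genes, 7 were lower and 2 higher at all 3 times, with SRM at -0.49, PPAN at -0.53 and NOLC1 at 0.43. Of 30 DNA replication genes 7 were higher and 3 lower at all 3 times, with E2F2 at 1.05, CDCA7 at 0.60 and TK1 at -0.42. MCM3 was at 0.94 (0.17, 1.98 and 0.67 by time) and its other probe at -0.17. Of 28 G2/M genes 7 were higher and 3 lower at all 3 times. PTTG1 was at 0.87 with its other probe at -0.04, and BUB1 was at 0.44. CENPE was at -0.49 with its other kept probe at 0.30. Among 22 cell cycle inhibitors 4 were higher and 3 lower at all 3 times. RB1 was at 1.17 (0.64, 0.75 and 2.12 by time), BTG1 at 0.58, RBL2 at 0.46 and CCNG1 at -0.41. CDKN1B, which encodes p27, was at 0.45 ± 0.23 (SE). The other kept CDKN1B probe was at -0.03. The adjusted p in camera was 0.210 for growth genes, 0.450 for replication genes, 0.361 for G2/M genes and 0.450 for inhibitors (limma).

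Stress, interferon and metabolic genes were tested in the same way. The 16 heat shock genes had the lowest list p, with a mean difference of 0.35, which ran from 0.13 to 0.50 over the alternatives and was 0.23 without HSPE1. They had medians of 0.02, 0.51 and 0.19 at 4, 8 and 12 h. This list did not pass camera (adjusted p = 0.0742, limma), and the adjusted p was 0.705 with an estimated correlation of 0.129 and 2 residual degrees of freedom. The chaperonin HSPE1 was at 2.22 ± 0.80 (SE), with 0.24, 1.33 and 5.09 by time, but its DMSO array of 12 h lay below the background threshold, and its other probe was at -0.78. HSPA1B, above background in 2 of 3 DMSO arrays, was at 0.63 and the co-chaperone BAG3 at 0.40. Of 21 p53 targets 6 were lower and 2 higher at all 3 times, with PHLDA3, above background in 2 of 3 pimasertib arrays, at -0.54 and GADD45A at -0.45, whose other probe was at 0.18 (list adjusted p = 0.220, limma). Of 27 interferon-stimulated genes 7 were higher and 1 lower at all 3 times, with IFI44L at 0.47, its other probe at 0.41, and PARP9 at 0.48, its other probe at 0.12 (list adjusted p = 0.602, limma). The JAK-STAT3 list, with IL10 at 0.45 and IL10RB at 0.44 and their other probes at 0.09 and 0.16, had an adjusted p of 0.639 (limma). IL21R of this list was at -0.32, and its other kept probe at 0.40.

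Of 23 amino acid response genes, the serine synthesis enzyme PHGDH was at 0.85, MTHFD2 at 0.55 and WARS1 at -0.61, whose other kept probe was at 0.20. GAPDH was at -0.54 and ENO1 at 0.44 among 20 glycolysis genes, and 2 other GAPDH probes were at 0.36 and -0.04. The sterol regulator SREBF2 was at -0.33 and FADS1 at 0.45 among 22 lipid synthesis genes. NDRG1 was at 0.37 and KDM4B at -0.33 among 17 hypoxia genes. CD74 was at -0.37 with other probes at -0.35 and -0.90, and RFXAP at 0.56, among 12 MHC class II genes. RPS19 was at -0.39 among 22 ribosomal protein genes, and RPL10A at 0.31, whose other probe was at -0.35. These 6 lists did not pass, with adjusted p of 0.846, 0.846, 0.939, 0.861, 0.407 and 0.861 in that order (limma). Median and mean differ in sign for glycolysis genes (-0.03 and 0.03) and for hypoxia genes (0.02 and -0.003). The 7 measured epithelial markers gave an adjusted p of 0.861 (limma). Markers of T cells, myeloid cells and fibroblasts had 4, 3 and 3 measured members, with medians of -0.20, 0.03 and 0.13, and were not tested.

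**Figure D2:**
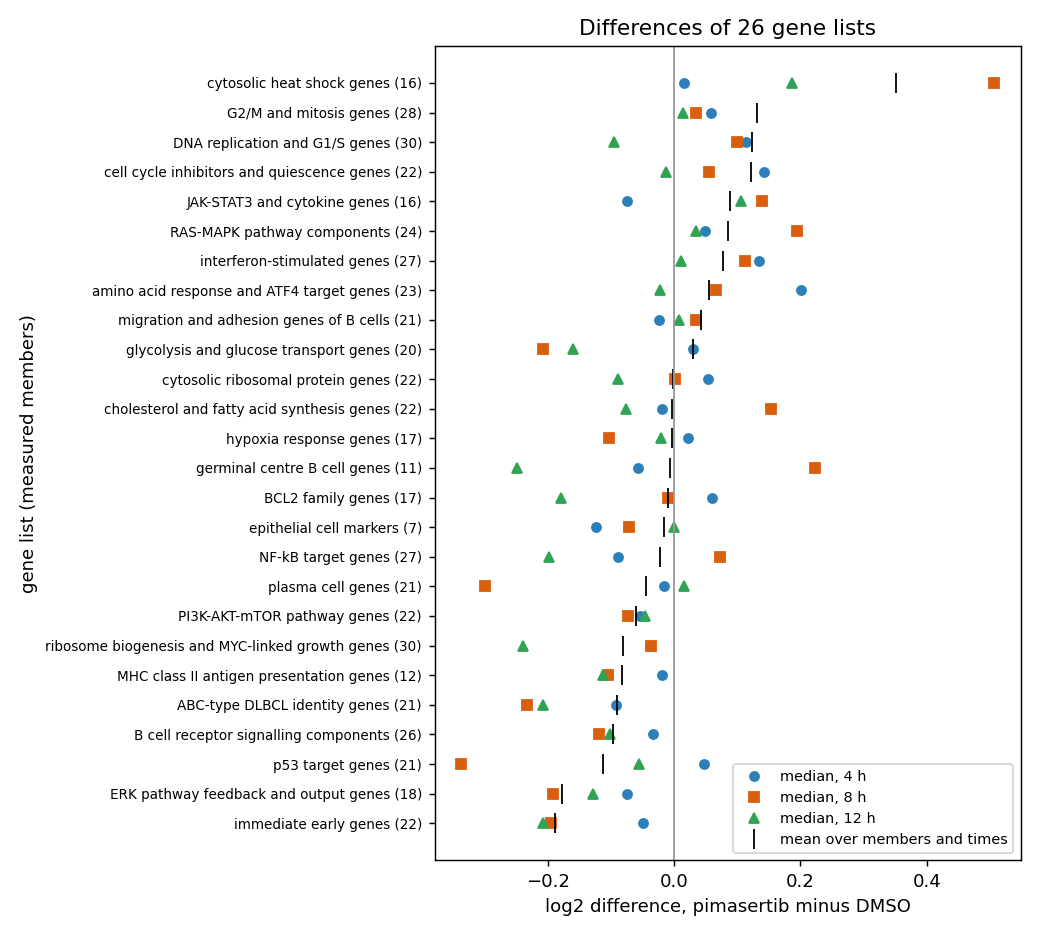
Log2 difference, pimasertib minus DMSO (horizontal axis), for 26 gene lists (vertical axis, with the number of measured members); circles, squares and triangles are the medians over members at 4, 8 and 12 h, and bars the mean over members and times. The mean of heat shock genes, raised by HSPE1, is 0.35, and immediate early genes farthest to the left at -0.19.

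Across the 26 lists, 0 passed an adjusted p of 0.05 in camera of limma, and 5 had an unadjusted p under 0.05. With an estimated correlation 0 passed, with 0 at an unadjusted p under 0.05. By fry 0 passed, with 5 at an unadjusted p under 0.05. Heat shock genes passed without a filter on dim probes (adjusted p = 0.0243) and without the 4 h pair (adjusted p = 0.0255), over a range of 0.0243 to 0.306 in limma. ERK feedback and output genes passed where all 6 arrays had to exceed background (adjusted p = 0.00814), over a range of 0.00299 to 0.258 in limma. With an estimated correlation no list passed in any of the 15 alternatives (lowest adjusted p = 0.546, limma). The few residual degrees of freedom, 2 in the main fit, made a pass hardly possible, so failing there does not by itself count against a list. For heat shock genes, however, the estimated correlation in the main fit, 0.129, was also well above the preset 0.01. Their p at the preset correlation may therefore be too small, also in the alternatives where they passed.

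At each time alone, differences have no replicate and no test. At 4 h, 4 genes were at least 2-fold lower and 4 at least 2-fold higher with pimasertib. Named after their values were seen, the lower genes were EGR1 at -1.45, PTPN6 at -1.40, CD69 at -1.08 and SGK1 at -1.04. The higher ones were EIF3CL at 1.44, the 18S ribosomal RNA gene RNA18SN5 at 1.43, the sodium pump subunit ATP1B1 at 1.01 and RRM2, a subunit of ribonucleotide reductase, at 1.004. At 8 h 748 genes were at least 2-fold higher and 135 lower, and at 12 h 312 higher and 142 lower. Between the DMSO arrays of 8 h and 4 h 97 genes were at least 2-fold higher and 704 lower, whereas between the pimasertib arrays of those times there were 2 and 0. Over all genes the differences at 4 h correlated with those at 8 h at 0.208 and at 12 h at 0.176, and those at 8 and 12 h at 0.0967, where genes are not independent replicates.

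**Figure D3:**
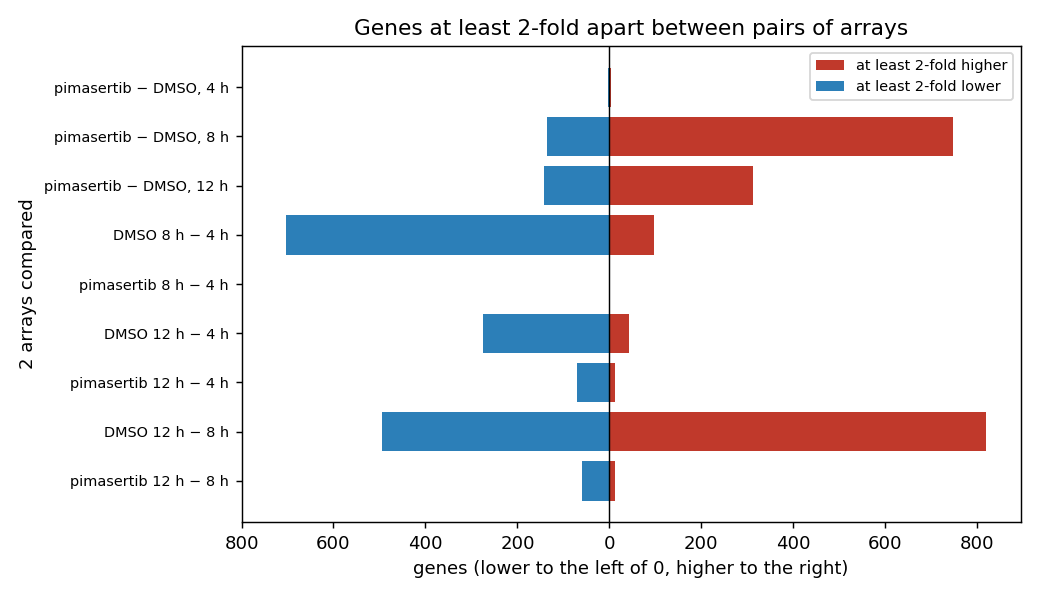
Number of genes (horizontal axis) at least 2-fold higher (red, right of 0) or lower (blue, left of 0) in the difference between 2 arrays named on the vertical axis. The DMSO array of 12 h against that of 8 h gave 818 higher and 495 lower genes, and the pimasertib array of 8 h against that of 4 h gave 2 and 0.

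The last question was whether the difference between treatments grew or shrank with time, and how DMSO cultures changed by themselves. For the treatment by time slope, 0 genes passed in limma (lowest adjusted p = 0.9999) and 178 had an unadjusted p under 0.05, against a 5% share of 553.4. With the noise of these arrays, 116 of 10869 unchanged simulated genes had such a p, so 178 is not read as below chance. With array weights, an alternative chosen after seeing the data, 172 genes passed for this slope and 429 for that of DMSO. The genes of smallest p with a rising difference were the cytochrome c oxidase subunit COX7C at 0.51 per hour, LPXN, a focal adhesion protein, at 0.42 and TMEM183BP at 0.42. Those with a falling difference were DHX33, an RNA helicase, at -0.34 per hour, EIF3CL at -0.25 and PKP4 at -0.25. None of these 6 passed. When the 12 h pair was left out, the mean difference of each of the 6 changed sign or by more than 1.5 times. COX7C, for example, was at -0.12, 1.15 and 3.93 at 4, 8 and 12 h. These values per hour therefore lean on 1 pair and need not be gradual trends. In simulated data with the noise of these arrays the slope test recovered 0 of 100 genes with a 4-fold growth over 8 h, so it could not show a change of that size.

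In DMSO alone, 0 genes had a slope that passed in limma (lowest adjusted p = 0.484) and 339 had an unadjusted p under 0.05, against a 5% share of 553.4. A chance count for this slope was not simulated. For the slope difference of the same model it was 116 of 10869, so 339 is not read as below chance. The genes of smallest p were LPXN at -0.44 per hour, TMEM183BP at -0.39 and PAFAH1B3 at -0.37. In the other direction they were EIF3CL at 0.21 per hour, RRM2 at 0.19 and ZFP36, which encodes the mRNA-destabilising protein tristetraprolin, at 0.14. Both slopes use the same DMSO arrays, so the genes named under both are not independent of each other.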

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

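The tests named in this part were chosen after the result was seen. RNA18SN5, the gene of 18S ribosomal RNA, was 1.43 and 1.97 higher on the log2 scale with pimasertib at 4 and 8 h and -1.39 at 12 h, so its differences span 3.36 and change direction between times. Each time rests on 1 array per treatment, and the difference between times was not tested for this gene alone.

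At 8 h 883 genes were at least 2-fold apart between treatments, 748 higher and 135 lower, while at 4 h there were 8. For 175 of them a second probe of the same gene, at a mean level of at least 7.49, could be read, and its 8 h difference was a median 0.0417 of that of the first probe (95% bootstrap interval -0.0386 to 0.0947). Over all 1332 genes with such a second probe, the differences of both probes correlated at 0.34 at 4 h, 0.0233 at 8 h and 0.0811 at 12 h, across genes. The pimasertib array of 8 h minus that of 4 h was a median 0.0183 of the 8 h difference (0.0129 to 0.0249), which argues against a change in the pimasertib cells between 4 and 8 h. This ratio does not bear on a change in DMSO cells that pimasertib held back. For the 748 higher genes, DMSO had a median of -1.23 at 8 h minus 4 h and 0.09 at 12 h minus 4 h. For the 135 lower genes these were 0.82 and -0.12. These medians argue against a DMSO change that lasted to 12 h. On a passing one only the second probes speak. Probe-specific noise on the DMSO array of 8 h is a candidate explanation that these values go with, and what would have made that array noisy stays open.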

How the results depend on the processing

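Array weights, cyclic loess, normexp, the stricter background threshold, the fit with both the DMSO array of 8 h and the time block left out, and estimated correlations in the alternatives were chosen after seeing the data. The count of genes past the threshold was 0; it was 2 (EGR1 and PTPN6) with a trended and robust prior and with the stricter threshold, and 4 with array weights and no time block. Leaving out each time pair gave 0 to 101; the 101 came without the 12 h pair, where 1 residual degree of freedom was left and the variances were pooled over all genes (median total degrees of freedom 11069, against 6.97 in the main fit). Without the time block it was 0 (lowest adjusted p 0.0833 in limma, 753 at an unadjusted p under 0.05), but the own-list calls of BIK and SGK1 were lost without this pairing by time (0.0572 and 0.0809). Without a filter 1372 genes had an unadjusted p under 0.05. The lists that passed numbered 1 with no filter (heat shock), 1 with all 6 arrays above background (ERK feedback), 0 to 1 on leaving out each pair, 2 with array weights and no time block (G2/M, interferon), 1 with both the DMSO array of 8 h and the time block left out (growth genes), and 2 with cyclic loess and with the stricter threshold (heat shock, ERK feedback). With an estimated correlation 0 lists passed in all 15 alternatives, where the few residual degrees of freedom made a pass hardly possible. Genes passing over their own list numbered 5; they were 10 with the trended prior, 6 to 15 on leaving out each pair (15 in that pooled fit), 11 with array weights, 17 with array weights and no time block, 3 with loess, 8 with normexp and 11 with the stricter threshold. PTPN6 passed in 15 of 15 alternatives, EGR1 and DUSP2 in 14, BIK and SGK1 in 9. At 4 h the lower genes numbered 2 with all 6 arrays above background; with normexp 8 were higher and 7 lower at 4 h, 229 lower at 8 h and 233 lower at 12 h; loess gave 72 lower at 8 h. With array weights 172 genes passed for the slope difference and 429 for the DMSO slope, with weights estimated from 2 residual degrees of freedom. The causes were not tested. Of 432 values of a part of the named genes under alternatives, 419 kept their side of the threshold and 13 now passed. For 388 list values these counts were 378 and 10. Signs changed without passing in 15 and 34, and 0 reversed. As 0 genes and 0 lists passed in the main fit, no call could be lost here. Of 74 values of the own-list calls, 13 lost the call and 61 kept it. EGR1 ranged from -2.25 to -1.63 and PTPN6 from -2.22 to -1.61. Median scaling, background corrections of raw intensities and a chip block were not run, because the columns of that table match no label. Genes near background, such as DUSP6, have little signal to show a change.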

Other observations

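In this part the tests on second probes and on swapped pairs were chosen after the result was seen, and the counts over splits of the arrays were planned. No difference between times was tested for the lists. In the 4 h pair, the quietest of the 3, some lists had medians far from those of random lists. There the median of 23 amino acid response and ATF4 target genes was 0.20, at percentile 99.98 of 10000 random lists of the same size and expression, with 17 members higher, among them the tRNA exporter XPOT at 0.80 and the amino acid transporter SLC7A5 at 0.44. Cell cycle inhibitors had a median of 0.14 (percentile 99.73, FOXO1 at 0.53) and interferon-stimulated genes 0.13 (percentile 99.55, 22 of 27 higher). NF-kB targets had -0.09 (percentile 1.73), with BCL2A1 at -0.77, LTB at -0.50 and RELB at -0.45, while 10 of 27 members were higher, among them CCR7 and IRF1 at 0.57. Genes of the activated B cell-like subtype had a median of -0.09 (percentile 2.23) but a mean of 0.01, with 10 of 21 higher. The 7 epithelial markers, of a cell type other than this B cell line, lay almost as far out at percentile 2.80. Of 26 lists, 5 lay in the outer 5% at 4 h, 3 at 8 h and 1 at 12 h, where chance gives 1.3. None of these 5 was as far out at 8 or 12 h. These percentiles describe 2 arrays and test nothing about the treatment.

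Genes with several kept probes offer a second reading. Of 2853 such genes, 173 had every kept probe on the same side at all 3 times (95 higher, 78 lower), against 83, 79 and 59 with the labels swapped in the 8 h pair, the 12 h pair or both. In 5 of them each probe averaged at least 1.5-fold, and these were SGK1 (lower, all 3 probes) and CD36, a fatty acid transporter, ABCB9, CRLF3 and AP1G1 (higher, both probes). SGK1 was at -0.95, -0.90 and -1.11 over its probes at 4, 8 and 12 h. The 4 higher genes lean on the 8 h pair, with CD36 at 0.27, 2.03 and 0.50, ABCB9 at 0.24, 1.39 and 0.89, CRLF3 at 0.36, 1.58 and 0.55 and AP1G1 at 0.36, 1.24 and 0.39, and without that pair all 4 averaged below 1.5-fold. CTNNB1, which encodes beta-catenin, was higher by 0.88, 0.51 and 0.27 at 4, 8 and 12 h, and MS4A6A, of a family of membrane proteins, was at -0.36, -0.98 and -0.79 over 3 probes. Apart from SGK1, these genes were named after their values were seen, and none of the genes passed over all genes.

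Whether the genes of smallest p rest on single probes was examined in both directions. For 4 of the 10 lower genes with another kept probe, the other probes gave a median 0.662 of the first probe's difference. This median includes TDP1 at 0.0352, whose other probes, at mean levels of 7.01 and 6.76, lie near background. The NFATC1 probe that gave 0.446 of the first is about as dim, at 6.99, so both readings are weak. The 3 genes besides TDP1 were at 0.561 for MMP7, 0.763 for NFATC1 and 1.08 for SGK1. For 4 of the 10 higher genes the median was 0.187. It includes POT1 at -0.0311, whose other probe has a mean level of 6.67, and a RHOT1 probe at a mean level that rounds to 6.70, both under the background threshold (the latter barely), so these ratios partly measure background. The single other probes of SEPHS1 and BTF3L4, well above it, stayed below 0.3 of the first. The 2 brighter others of RHOT1 had log2 differences of 0.09 and 0.67, against 0.76 for the first, and the higher was 0.883 of it. With so few readable probes, probe-specific noise cannot be told apart from a difference of transcript forms in either group. The first probes were also of genes picked for the smallest p in these same data, which by itself tends to lower such ratios.

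At least 1.5-fold apart in the same direction at all 3 times were 12 genes, and swapping labels within pairs gave at most 5, so 1 of 4 arrangements reached the real count. With 4 arrangements the share cannot fall below 0.05. The 10 splits of the 6 arrays are also too few for that. The count of genes past the threshold was 0, and the highest of the other splits gave 0. The treatment by time slope likewise gave 0 and 0. For lists the real count was 0 and the highest other 1. Any split reaches a count of 0, so the 10 of 10 found for each of these counts was fixed in advance and shows nothing. At an unadjusted p under 0.05 the real split gave 831 genes and the highest other split 2161, with 5 of 10 as large. With time as a block, splits that part only 1 pair repeat each other. Among those 5, counts of 2161 and 921 each came from 2 such splits, which are not separate tests. The splits with 2161 set the DMSO array of 8 h against the pimasertib array of 8 h while keeping both arrays of each other time together, which points to the structure of that pair. Of the 4 splits that part every time pair, the other 3 gave 224 to 327.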
